A study of Mus musculus with 12 samples.

How the data were processed

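The series held 12 dual-colour Agilent microarrays of mouse skin in 4 groups of 3. Per the file headers, the scanner files gave spot and local background brightness as intensity in each dye, extracted with Agilent Feature Extraction 11.5.1.1. The same files gave processed intensity, which per the file headers was background subtracted, detrended and dye-normalized by that program, and a log10 ratio of processed Cy5 over processed Cy3. Cy5 carried the skin RNA and Cy3 a universal mouse reference RNA that was shared by all arrays, without a dye swap. The authors also deposited a log2 table by gene name for the whole series. Its columns were checked against the scanner files and held skin over reference, although its title named the dyes in the other order.

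Values were computed from the scanner files with limma 3.58.1 in R 4.3.3. Mean spot signals were corrected for local background by the normexp method with an offset of 50. Loess normalization was run within each array with control spots at weight 0, and no scaling was applied between arrays. Control spots and spots marked as outliers by the extraction program were left out, and the spots of a probe were averaged. A probe was kept where Cy5 was well above background on at least 3 of the 12 arrays. Of 39429 distinct probes, 27014 were kept, and they stood for 20320 genes. Of the kept probes, 1131 had no value on some array because a spot was left out. Their group means and checks of overlap used the remaining arrays. Gene names came from the RefSeq table or, failing that, from the scanner files. A gene with several kept probes, of which there were 5318, was represented by the probe of highest average intensity. Positions refer to the mm9 build named in the scanner files.

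Depth was described by Cy5 signal over background. The number of arrays limits the precision. Group means were fitted for all 12 arrays together with lmFit and eBayes, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. There were 4 contrasts: mimic against PBS in incised skin, antimiR against PBS in intact skin, incised against intact skin under PBS, and the mimic effect minus the antimiR effect. Errors given after a log2 fold change are standard errors from this fit. All adjusted p values for genes are limma's, and all are 2-sided.

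A total of 30 gene lists, written from general knowledge before the data were examined, were tested in each contrast with camera at a preset correlation of 0.01. The 30 p values of a contrast were adjusted together. They covered matrix genes listed as miR-29 targets, other listed miR-29 targets, collagens, collagen processing, matrix glycoproteins, TGF-beta response, matrix proteases, inflammatory cytokines, interferon response, cell cycle, p53 response, immediate early genes, and hypoxia with glycolysis. They also covered keratinocyte activation, epidermal differentiation, basal keratinocytes, ribosomal proteins and subunits of oxidative phosphorylation. The rest were markers of fibroblasts, macrophages, neutrophils, T or NK cells, mast cells, endothelium, smooth muscle with pericytes, skeletal muscle, adipocytes, hair follicles, melanocytes and Schwann cells. Camera with a correlation estimated from the arrays and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way. In the main fit camera and fry used only the 19415 genes with a value on all 12 arrays, while medians and counts used all measured members. The tests thus held 22 of 23 matrix targets, 26 of 28 interferon genes, 15 of 19 skeletal muscle markers and 17 of 22 oxidative phosphorylation genes. A list score per array is the median over the list of the log2 ratios, each gene centred over the 12 arrays.

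Genes named in the text followed a rule. In each of the first 3 contrasts these were the 8 called genes with the largest rise and the 8 with the largest fall among those whose groups of 3 arrays did not overlap, without RIKEN, predicted or unnamed genes. The others were up to 4 members of smallest p from each list described, and in the contrasts of mimic and antimiR also Col1a1, Col1a2, Col3a1, Eln, Fbn1, Dnmt3a, Dnmt3b and Mcl1. In the difference between effects they were the 4 largest each way. Some genes that meet this rule are not named. This rule, the tests of the 4 contrasts and of the lists, and all alternatives but one were set before the data were examined. Several tests of explanations were chosen afterwards, and the closing section names them.

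The arrays lay on 3 slides of 4, read from the file names. Slide 1 held the 3 incised PBS arrays and mimic array 1. Slide 2 held mimic arrays 2 and 3 and intact PBS arrays 1 and 2, and slide 3 held intact PBS array 3 and the 3 antimiR arrays. The alternatives were no background correction, the program's processed signals, scaling between arrays, Cy5 alone, the deposited table, no filter on dim probes, a filter on all 12 arrays, the mean over probes, only the compared groups in the fit, trend with robust moderation, array weights, slide as a fixed or a random block, the replicate number as a block, and leaving out each array. Taking the probe nearest the downstream end of a transcript was added after the data had been seen. For pairs of probes of a gene at least 500 bp apart, the upstream minus the downstream log2 ratio was taken on each array. A planned comparison of genes with and without a miR-29 seed match in the 3′ UTR was not run, since no UTR sequences were at hand.

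The pipeline was tested on simulated data of 19415 genes with 200 changed genes. Of the genes changed by 1 on the log2 scale, 83.6% were recovered in the mimic contrast and 70.1% in the antimiR contrast. Of the calls, 4.05% and 6.80% were false, and 9.20% in the wound contrast. The genes were simulated independently and without slide effects, so these shares are not error rates of the real calls. Figures were drawn with matplotlib 3.10.9.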

Results

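Gene expression was measured in the skin of male C57BL/6 mice of about 8 weeks. The 12 samples formed 4 groups of 3. Incised skin, with a sutured wound of 1 cm, received PBS or 100 nmol of a miR-29 mimic 72 h after wounding. Intact skin received PBS or 100 nmol of antimiR-29, an oligonucleotide that binds and blocks miR-29. Skin was taken 24 h after the injection. Cy5 was well above background at 65.7 to 73.9% of 39429 probes per array, its signal was 3.63 to 4.99 times the background, and 0 spots were saturated. Intact PBS array 3 stood apart from its group, with a median correlation of 0.921 across genes to the other arrays of the group, against 0.939 or more for every other array. Its adipocyte marker score was 1.30 and its score for matrix genes listed as miR-29 targets was -0.62. Incised PBS array 2 and mimic array 3 also had high adipocyte scores, of 1.1 and 0.61. Intact PBS array 2 had a hair follicle score of 2.41, against scores from -0.33 to -0.07 on the other arrays. The first principal component held 41.6% of the variance and separated incised from intact skin.

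The mimic comparison asked what added miR-29 changed in a healing incision. miR-29 represses many collagen and other matrix genes. Among called genes the largest fall was in Sfrp4, a secreted Wnt modulator, at -2.76 ± 0.30 (adjusted p = 0.0085, probe on chromosome 13, 19724488 to 19724547). Its log2 ratio over the reference went from 3.27 ± 0.08 under PBS to 0.51 ± 0.45 under mimic (SD, n = 3 each). Pi16 and Clec3b, both expressed by dermal fibroblasts, fell by 1.59 ± 0.22 and 1.52 ± 0.25 on the log2 scale (adjusted p = 0.019 and 0.030). The fibroblast gene Dpt fell by 0.83 ± 0.15. Among called genes with a gene name the largest rise was in Mmp8, a neutrophil collagenase, at 2.15 ± 0.38 (adjusted p = 0.038; chromosome 9, 7568238 to 7568297). In all, 41 genes were higher and 78 lower with mimic among 20320 tested. Over all genes tested the groups of 3 arrays did not overlap for 24.1%, against 10% by chance.

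Some of the other genes that fell are expressed in muscle. The dual-specificity phosphatase gene Dupd1 fell by 1.94 ± 0.24 on the log2 scale, Mrln, which encodes a regulator of the muscle calcium pump, by 1.61 ± 0.20, and Synm, a gene of an intermediate filament protein, by 1.42 ± 0.17. Of the skeletal muscle markers, Pvalb fell by 0.65, Myh1 by 0.56 and Atp2a1 by 0.89, while Casq1 was at -0.88 with an adjusted p of 0.061. Tceal7 fell by 1.80 and Sema6c by 1.34, though another Sema6c probe gave -0.35. Beside Mmp8, the genes that rose most included the chitinase-like Chil4 at 1.83 ± 0.31, the scavenger receptor gene Msr1 at 1.39 ± 0.24, Slfn1 at 1.24, the cytokine gene Tnfsf14 at 1.15 and Pram1 at 1.14. The metallothionein gene Mt2 rose by 1.40, with no value on mimic array 3. The noncoding Mirt1 rose by 1.37, but its other probes gave 0.09 to 1.26.

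Of the 23 matrix genes listed as miR-29 targets, all had negative values, with a median of -0.69 (camera adjusted p = 2e-09, 0.25 with an estimated correlation, and 0.081 with fry). None passed the threshold over all genes tested, and 9 were lower when adjusted over the list alone. Col1a1 was at -1.28 ± 0.51 (adjusted p = 0.34), Col1a2 at -1.28 ± 0.44 (0.25), Col3a1 at -1.45 ± 0.57 (0.33), Eln at -0.74 ± 0.26 (0.25) and Fbn1 at -1.07 ± 0.47 (0.38). The members of smallest p were Sparc at -0.97, Pxdn at -0.77, Col5a2 at -1.05 and Lamc1 at -0.50, with adjusted p from 0.12 to 0.18. The other 34 listed targets had a median of -0.14 (adjusted p = 0.088). Among them Tgfb3 was at -0.96 (0.066), Fstl1 at -1.09 (0.16), and the methyltransferase gene Dnmt3a at -0.51 ± 0.14 (0.15). Dnmt3b was at -0.01 and the survival gene Mcl1 at 0.16.

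**Figure D1:**
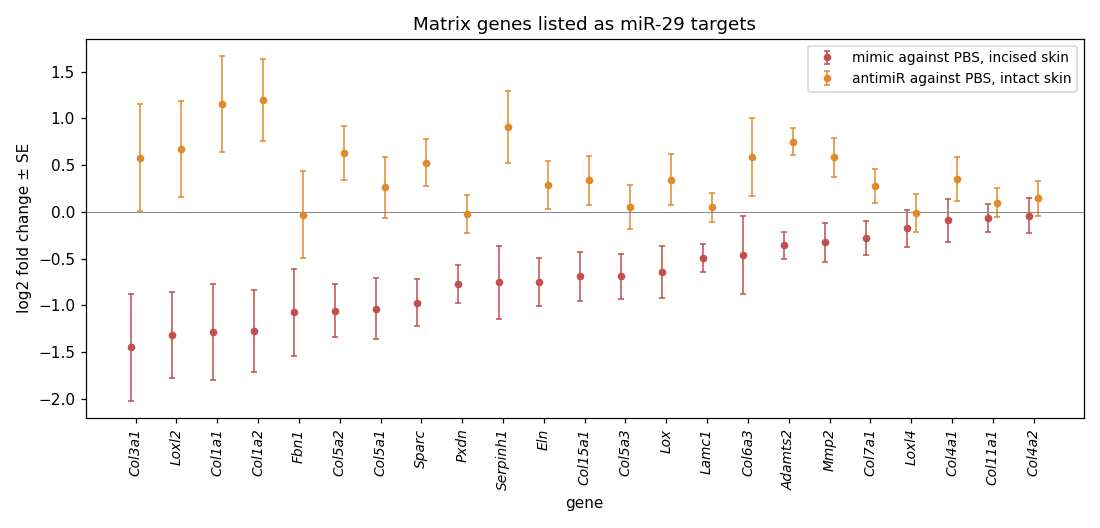
Log2 fold change with its standard error (3 arrays per group, except Loxl2 without intact PBS array 1) for each of the 23 matrix genes listed as miR-29 targets, for mimic against PBS in incised skin and antimiR against PBS in intact skin. All 23 lie below 0 with mimic and 20 lie above 0 with antimiR, with medians of -0.69 and 0.35.

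The lower matrix values came with lower markers of fibroblasts and muscle. Fibroblast markers had a median of -0.80, with 3 of 12 called and 8 lower when adjusted over the list alone (camera adjusted p = 9.6e-10, and 0.094 with an estimated correlation; fry 0.0085). Skeletal muscle markers had a median of -0.64, with 3 of 19 called and all 19 lower when adjusted over the list alone. Over the 15 of these with a value on every array, without Pvalb and Myh1, camera's adjusted p was 9.6e-17. It was 0.19 with an estimated correlation and 0.014 with fry. Medians were also lower for collagens (-0.30), matrix glycoproteins (-0.44), collagen processing (-0.24), TGF-beta response (-0.16), adipocyte markers (-0.41), oxidative phosphorylation (-0.21) and epidermal differentiation (-0.19). Medians were higher for inflammatory cytokines (0.52), interferon response (0.34), cell cycle (0.22) and neutrophil markers (0.17). Of the 19 macrophage markers (median 0.13), 12 were positive and 7 negative, with 1 called higher and 4 higher when adjusted over the list alone. That list and T or NK markers (-0.14) did not pass (camera adjusted p = 0.088 each). Each of the other 11 passed camera, with adjusted p from 1.1e-07 to 0.039, and none did with an estimated correlation, where their adjusted p ran from 0.24 to 0.70. Over 15 processing alternatives the TGF-beta call ended in 7 (medians from -0.16 to -0.03), the epidermal call ended or reversed in 3 (-0.23 to 0.04), the neutrophil call ended in 3 (0.08 to 0.26) and the adipocyte call in 2 (-0.72 to -0.25). Several calls also ended when 1 array was left out. Without incised PBS array 1 the cell cycle median was 0.12. Without incised PBS array 2 the medians were 0.11 for interferon response, -0.16 for TGF-beta response and 0.13 for adipocyte markers, and without incised PBS array 3 they were 0.31 for interferon response, -0.17 for TGF-beta response and -0.11 for epidermal differentiation. Without mimic array 1 interferon response was at 0.24 and adipocyte markers at -0.29, without mimic array 2 interferon response was at 0.22, cell cycle at 0.11 and adipocyte markers at -0.08, and without mimic array 3 TGF-beta response was at -0.07. Other medians moved and kept their calls. Without incised PBS array 1 interferon response was at 0.57 and adipocyte markers at -0.66, and without incised PBS array 2 inflammatory cytokines were at 0.30, oxidative phosphorylation at -0.13 and epidermal differentiation at -0.34. Without mimic array 1 neutrophil markers were at 0.08, and without mimic array 3 inflammatory cytokines were at 0.33, interferon response at 0.53, cell cycle at 0.38 and adipocyte markers at -0.86.

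Slide and single arrays limited this comparison. Within slide 1 the skeletal muscle median was -0.36 (1 mimic against 3 PBS arrays), against -0.64 over all arrays. With slide as a fixed block limma called 0 genes, with 1471 at an unadjusted p under 0.05, while the medians were -0.64 for the matrix targets and -0.71 for the fibroblast markers, the same as within slide 1 (1 mimic against 3 PBS arrays). Leaving out an array left 1 gene (without incised PBS 1), 22 (incised PBS 2), 7 (incised PBS 3), 53 (mimic 1), 13 (mimic 2) or 31 (mimic 3), and each gene call named above but that of Pram1 ended in at least 1 of these 6 fits.

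The antimiR comparison asked what blocking miR-29 changed in intact skin. Interferon-induced genes rose: Isg15 by 3.12 ± 0.47 (adjusted p = 0.0025; chromosome 4, 155573649 to 155573708), Dhx58 by 2.20 ± 0.19, Xaf1 by 1.93 ± 0.21, Stat2 by 1.79 ± 0.21 and Parp14 by 1.60 ± 0.18. Among called genes the largest rise was in Slfn4, a gene of activated myeloid cells, at 3.51 ± 0.61 (adjusted p = 0.0052). Its log2 ratio went from -0.35 ± 1.08 to 3.16 ± 1.07 (SD, n = 3 each). Among 28 interferon response genes the median was 1.97, with 26 called and 27 higher when adjusted over the list alone (camera adjusted p = 2.8e-24, and 0.67 with an estimated correlation; fry 0.0035). Within slide 3 (3 antimiR arrays against 1 PBS array) the median was 2.13. In all, 1063 genes were higher and 923 lower, and over all genes tested the groups did not overlap for 25.7%, against 10% by chance.

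Some genes of chemokines and acute-phase proteins rose. The log2 fold changes were 3.24 ± 0.43 for Ccl4, 2.74 ± 0.45 for Ccl12, 2.20 ± 0.25 for Ccl3, 2.76 ± 0.70 for Saa3 and 2.56 ± 0.60 for Saa1. Ccl3 had no value on antimiR array 2, and with Cy5 alone it was at -0.33. Inflammatory cytokines had a median of 0.79 with 8 of 24 called and 9 higher when adjusted over the list alone (adjusted p = 0.00032, and 0.67 with an estimated correlation), and without intact PBS array 3 the median was 0.38. The myeloid receptor genes Cd300lf and Sirpb1b rose by 3.38 and 2.83, with 0.79 to 3.11 at the other Cd300lf probes, and Clec4d rose by 1.73. The macrophage genes Fcgr1, Trem2, Gpnmb and Cd68 rose by 2.49, 1.47, 1.41 and 1.25, yet the 19 macrophage markers had a median of 0.27 (adjusted p = 0.15). Genes of matrix-degrading enzymes rose, Mmp3 by 2.36 ± 0.35, Mmp8 by 1.87 ± 0.38 and Ctss by 1.41 ± 0.29, and their list had a median of 0.29 (adjusted p = 0.034, and 0.67 with an estimated correlation). That call ended in 6 of 15 processing alternatives (medians from 0.21 to 0.53) and without intact PBS array 3 or antimiR array 1, with medians of 0.23 each, and without intact PBS array 1 the median was 0.48.

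Falls among called genes were led by Ccl24, an eosinophil chemokine gene, at -2.45 ± 0.38 (adjusted p = 0.0031, chromosome 5, 136046667 to 136046726). The lymphatic and macrophage gene Lyve1 fell by 1.74 ± 0.44 on the log2 scale and the B-cell chemokine gene Cxcl13 by 1.71 ± 0.43. Muscle genes fell again, with Dupd1 at -1.96, Myh1 at -0.49 (no value on antimiR array 3) and Acta1 at -0.58. Muscle markers had a median of -0.36 with 3 of 19 called (camera adjusted p = 4.9e-06, and 0.67 with an estimated correlation). Lrtm1 fell by 2.00, the kinase gene Dstyk by 1.72 ± 0.11, Zbed6 by 1.67 ± 0.15 and the sorting nexin gene Snx27 by 1.86 ± 0.15, with -0.45 at another Snx27 probe. Subunits of oxidative phosphorylation had a median of -0.32 with 4 of 22 called, among them Atp5a1 at -0.52 and Atp5h at -0.34 (list adjusted p = 3.6e-06, and 0.67 with an estimated correlation).

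The 23 matrix targets had a median of 0.35 with antimiR, of which 1 was called (camera adjusted p = 0.017, and 0.77 with an estimated correlation; fry 0.22). Col1a1 was at 1.15 ± 0.51 (adjusted p = 0.20), Col1a2 at 1.20 ± 0.44 (0.12), Col3a1 at 0.58 ± 0.57 (0.60), Eln at 0.29 (0.55) and Fbn1 at -0.03 (0.98). Serpinh1, a collagen chaperone gene, was at 0.91 and the gelatinase gene Mmp2 at 0.58. The procollagen protease gene Adamts2 rose by 0.75 ± 0.14, with -0.34 at its other probe. This shift rested on intact PBS array 3: without it the median was 0.18 (adjusted p = 0.24) and Col3a1 was at -0.21, and within slide 3, where it was the control, the median was 0.69. The log2 ratio of Col1a1 was 0.44 on intact PBS array 3, against 2.17 and 2.71 on the other intact PBS arrays. That of Col1a2 was 0.46 there, against 1.90 and 2.43. Without antimiR array 1 the list's median was 0.24 (adjusted p = 0.19), and without intact PBS array 2 it was 0.54. The other listed targets had a median of 0.06 with calls both ways (adjusted p = 0.68). Pdgfrb rose by 1.28 ± 0.13, Pik3r1 fell by 0.66, and Dnmt3a, Dnmt3b and Mcl1 were at 0.33, 0.34 and 0.25. Tdg was at -1.10, but its other probes reached 0.35.

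Upstream probes of a gene lost signal against downstream probes in the antimiR arrays. Over 4188 pairs the median difference in log2 fold change was -0.14, from -0.11 for probes 0.5 to 2 kb apart to -0.16 for those over 20 kb apart, against 0.00 with mimic and 0.05 for wounding. With the downstream probe in place of the brightest 1839 genes were called, of which 1728 were called the same way at the brightest probe. Where the 2 probes differed, 60 of 263 genes called at the brightest probe were called the same way at both, against 110 of 348 for wounding. The probe held a polyadenylation signal (AATAAA or ATTAAA) in 26.0% of genes called higher, 9.10% of those called lower and 19.4% of those not called. With mimic the split was the other way, with 14.6% of 41 genes called higher and 32.1% of 78 called lower. For wounding the shares were 19.2% and 18.3%.

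**Figure D2:**
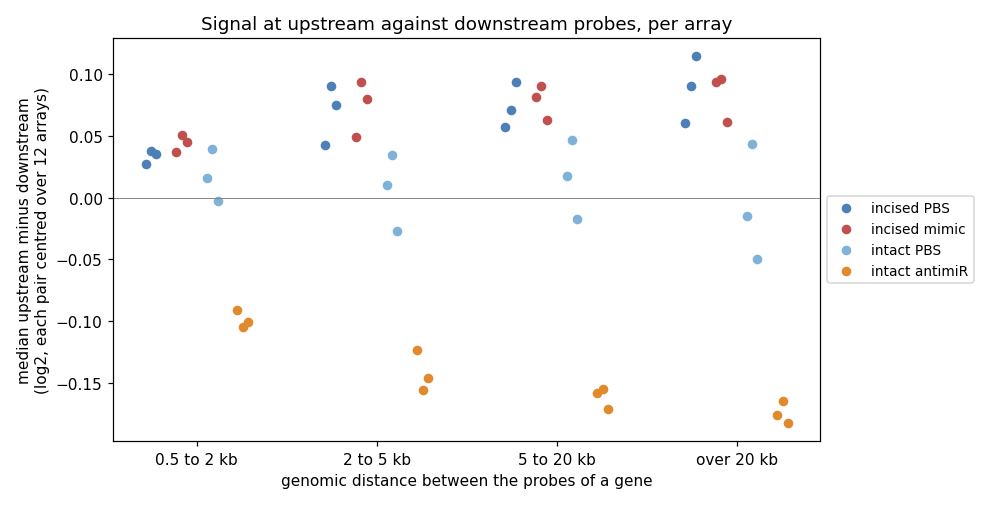
Median upstream minus downstream log2 ratio per array, each probe pair centred over the 12 arrays, by the genomic distance between the probes. The 3 antimiR arrays lie below the other 9 at every distance, with group differences from intact PBS of -0.11, -0.14, -0.15 and -0.16.

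Other lists that passed camera with antimiR were T or NK markers (median 0.20, adjusted p = 0.012), melanocyte markers (0.97, adjusted p = 0.025), adipocyte markers (-0.56, adjusted p = 0.025) and epidermal differentiation (-0.15, adjusted p = 0.039). With an estimated correlation their adjusted p ran from 0.67 to 0.77. In the melanocyte list Mlana rose by 1.36 and Dct by 1.32. Over 15 processing alternatives the T or NK call ended in 3 (medians from 0.18 to 0.36), the melanocyte call in 5 (0.16 to 1.35), the adipocyte call in 5 (-1.33 to -0.28), and the epidermal call ended or reversed in 8 (-0.32 to 0.25). These 4 calls also ended without some arrays: T or NK markers without intact PBS array 3 (0.24), melanocyte markers without antimiR array 1 (0.73), adipocyte markers without intact PBS array 3 (-0.19), antimiR array 1 (-0.46) or antimiR array 3 (-0.43), and epidermal differentiation without intact PBS array 1 (-0.10), intact PBS array 2 (-0.06) or antimiR array 3 (-0.14). Epidermal differentiation was at -0.45 without intact PBS array 3 and T or NK markers at 0.37 without intact PBS array 2. With slide as a fixed block the epidermal median was 0.25. Fibroblast markers had a median of -0.36 (adjusted p = 0.073), hair follicle markers -0.61 (0.069) and neutrophil markers 0.21 (0.10). With slide as a fixed block the antimiR contrast set 3 antimiR arrays against intact PBS array 3 alone. That array stood apart from its group, so this fit does not show that the calls are independent of slide. Without antimiR array 2 the count of called genes was 1.1e+03 when rounded (600 higher, 505 lower). With 1 array left out the calls of Saa1, Saa3, Clec4d, Gpnmb, Lrtm1, Lyve1, Cxcl13, Myh1, Acta1, Atp5h, Pik3r1 and Dct ended in at least 1 of 6 fits.

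**Figure D3:**
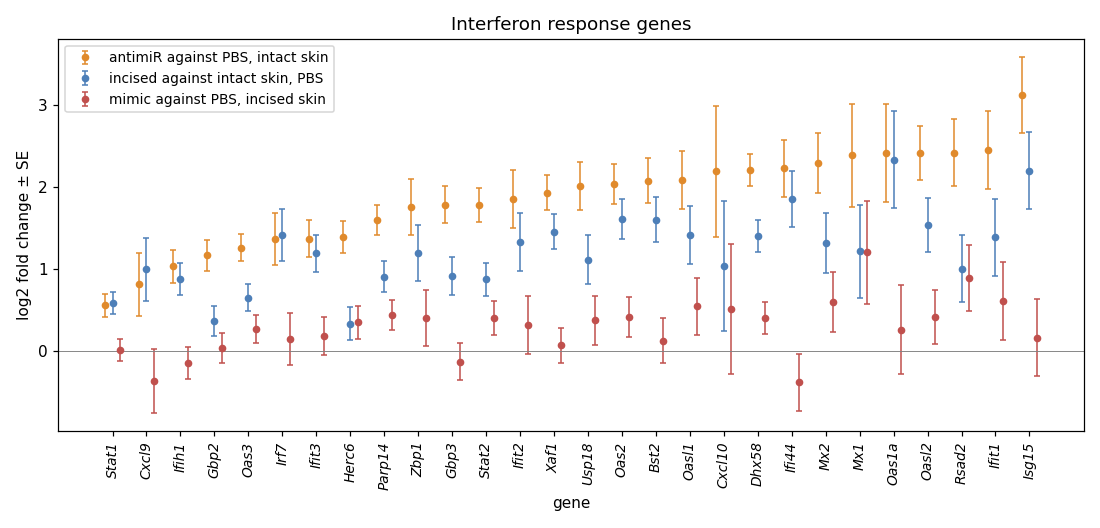
Log2 fold change with its standard error (up to 3 arrays per group) for each of the 28 interferon response genes measured, for antimiR against PBS in intact skin, incised against intact skin under PBS, and mimic against PBS in incised skin. Of the 28 genes, 26 had a value on every array. The medians are 1.97, 1.21 and 0.34.

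The comparison of the PBS groups gave the effect of the incision 4 days after wounding. Neutrophil chemokine and matrix protease genes rose: Cxcl5 by 4.19 ± 0.79 (adjusted p = 0.0072, chromosome 5, 91190490 to 91190549), Mmp13 by 3.31 ± 0.59, Mmp9 by 2.21 ± 0.33 and the cathepsin gene Ctss by 2.13 ± 0.29. The metalloproteinase inhibitor gene Timp1 rose by 1.70 ± 0.26. Macrophage genes rose, with Trem2 at 2.79 ± 0.17, Ms4a7 at 2.73 ± 0.36, Fcgr1 at 2.13 ± 0.30 and Arg1 at 1.94 ± 0.29, and S100a9, a gene of neutrophils and activated keratinocytes, rose by 1.93 ± 0.24. In all, 2015 genes were higher and 1125 lower, and over all genes tested the groups did not overlap for 35.1%, against 10% by chance.

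Slow-muscle troponin genes Tnnc1 and Tnnt1 rose by 3.31 ± 0.32 and 3.09 ± 0.62. Csta3 rose by 3.27, and Mest, Gsdmc3 and Uox by 3.44, 3.11 and 3.03, with lower values at their other probes (0.71 to 2.63 for Mest, 1.43 and 1.25). The interferon genes Oas2, Bst2, Xaf1 and Dhx58 rose by 1.62, 1.60, 1.46 and 1.41, with 0.34 at the other Xaf1 probe. Of the matrix targets, Col3a1 rose by 1.88 ± 0.57, Serpinh1 by 1.27 ± 0.39, Col5a2 by 1.05 ± 0.29 and Col5a3 by 0.93 ± 0.24, and the list had a median of 0.64 (adjusted p = 0.10). With 1 array left out Col3a1 ran from 1.09 to 2.41, Serpinh1 from 0.68 to 1.60, Col5a2 from 0.82 to 1.20, Col5a3 from 0.73 to 1.08 and Csta3 from 1.94 to 4.01, lowest without intact PBS array 3 except for Col5a3 (incised PBS array 2). Calls held only without intact PBS array 2 for Col3a1, without an intact PBS array for Serpinh1, without intact PBS array 1 or 2 for Col5a2 and Csta3, and without incised PBS array 1 or intact PBS array 2 for Col5a3. The matrix glycoprotein genes Tnc and Ltbp2 rose by 1.20 and 1.12. Falls were in Il22ra2, which encodes a soluble IL-22 antagonist, at -2.61 ± 0.44, Cyp1a1 at -2.39, the epidermal metallothionein gene Mt4 at -2.21, Ereg at -2.04, Calm5 at -1.91 and Scn2a at -1.86, with -1.59 and -0.43 at other Scn2a probes. Calm5 had no value on incised PBS array 3. Nerve sheath genes fell, Prx by 1.85 ± 0.48, Ngfr by 0.83 and Sox10 by 0.62. The immediate early genes Dusp1, Nr4a1 and Myc fell by 1.51, 1.49 and 0.58. The calls of Gsdmc3, Cyp1a1, Prx, Ngfr, Sox10 and Nr4a1 also ended in at least 1 of the 6 fits.

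Of the 30 lists, 14 passed camera. Medians were higher for interferon response (1.21), inflammatory cytokines (1.02), neutrophil markers (0.94), macrophage markers (0.79), keratinocyte activation (0.68), cell cycle (0.67), matrix proteases (0.53), matrix glycoproteins (0.49), TGF-beta response (0.33) and T or NK markers (0.27). They were lower for Schwann cell markers (-0.93), hair follicle markers (-0.71), immediate early genes (-0.49) and oxidative phosphorylation (-0.29). Adjusted p ran from 7.3e-12 to 0.013, and with an estimated correlation from 0.48 to 0.69. Fry called 7 lists. Without intact PBS array 2, which had the high hair follicle score, the hair follicle median was -0.13 (adjusted p = 0.47), and without intact PBS array 3 the neutrophil and T or NK medians were 0.80 and 0.20 and no longer passed. Without that array cell cycle was at 0.29, keratinocyte activation at 0.42, matrix glycoproteins at 0.32 and oxidative phosphorylation at -0.19, without intact PBS array 1 immediate early genes were at -0.30, and without incised PBS array 1 inflammatory cytokines were at 0.68. The PBS groups shared no slide, so a wound effect adjusted for slide runs through the mimic arrays. On slide 1 that link is mimic array 1 alone. With slide as a fixed block 11 genes were called, the interferon, inflammatory and macrophage medians were 0.91, 0.79 and 0.70, and 6 of the 14 lists no longer passed.

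The mimic and antimiR effects were compared directly, since opposite effects would be looked for in miR-29 targets. Among the named genes the difference was largest in Ccl24 (2.76 ± 0.54, adjusted p = 0.038), Snx27 (2.10), Frmd4b (1.97) and Dstyk (1.84), and most negative in Ifi44 (-2.60 ± 0.48, adjusted p = 0.031), Tgtp2 (-2.15), Vmn1r65 (-2.11) and Bst2 (-1.95). Other probes gave 0.78 for Snx27, 0.19 for Frmd4b and -0.30 for Tgtp2. Snx27 had no value on incised PBS array 2. The listed target Pdgfrb had a difference of -1.39 ± 0.19 (adjusted p = 0.0096). Within slides it was at 0.11 with mimic (1 mimic against 3 PBS arrays) and 1.08 with antimiR (3 antimiR arrays against 1 PBS array). Matrix targets had a median difference of -1.03, with 1 called and 15 lower when adjusted over the list alone. Among them Adamts2 was at -1.11 (adjusted p = 0.029), Sparc at -1.50 (0.079), Col5a2 at -1.68 (0.084) and Col1a2 at -2.47 (0.093). The other Adamts2 probe was at -0.33 with mimic and -0.34 with antimiR, so the called difference was not seen there. With 1 array left out the calls of Ccl24, Ifi44, Tgtp2, Bst2 and Adamts2 ended in at least 1 of 12 fits. In all, 131 genes had a higher and 94 a lower effect of mimic than of antimiR.

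Across genes, which are not independent replicates, the 2 effects went the same way more often than not. Pearson's r was 0.37, Spearman's rho 0.30, and 59.1% of genes had the same sign. Of the called genes, 26 were higher in both and 15 lower in both, where 2.14 and 3.54 would be shared if the calls were independent. None was called in opposite directions by limma. The shared rises included Mmp8, Slfn1, Plek, S100a4 and Bax, and the shared falls Dupd1, Mrln, Myh1 and Scara5, which were picked from the shared genes after their values were seen.

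**Figure D4:**
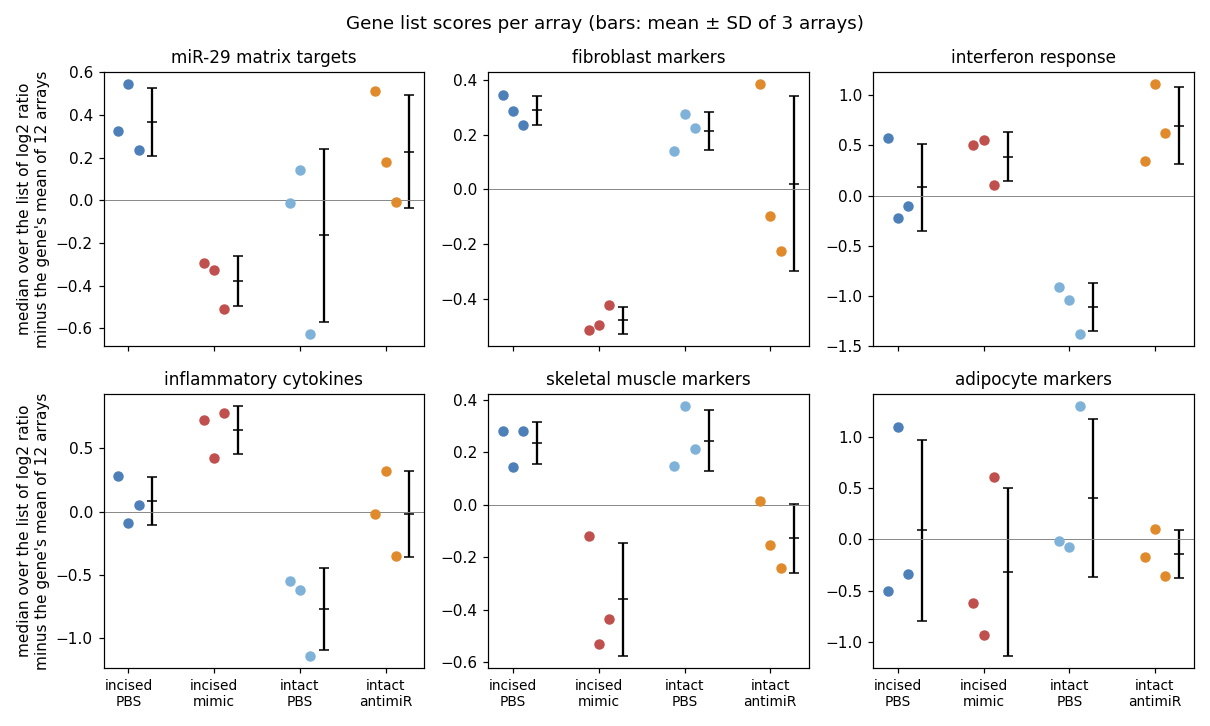
Score of 6 gene lists on each of the 12 arrays, as the median over the list of log2 ratios centred over all arrays, with the mean and SD of each group of 3. Mimic arrays lie lowest for fibroblast markers, and intact PBS array 3 stands apart for matrix targets (-0.62) and adipocyte markers (1.30).

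The remaining lists passed in none of the 4 contrasts. Their medians, for mimic, antimiR and wounding in this order, were 0.07, -0.18 and -0.28 for p53 response, -0.06, -0.22 and 0.21 for hypoxia with glycolysis, 0.15, -0.17 and -0.11 for basal keratinocytes, and -0.25, 0.00 and -0.06 for mast cells. They were 0.03, 0.14 and 0.18 for endothelium, -0.09, 0.11 and -0.02 for smooth muscle with pericytes, and 0.04, 0.03 and 0.04 for ribosomal proteins. The test's sign differed from the median's for 3 lists with mimic, 1 with antimiR, 2 with wounding and 2 in the difference, all of them lists that did not pass.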

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

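The tests of probe position, of slide and shorter RNA for the matrix targets, and of leukocytes and oligonucleotides for the interferon genes were chosen only after the results were seen.

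The mimic effect and the antimiR effect differed for 225 genes by limma's test of the difference itself. In the same test 9 of 30 gene lists differed. The median difference was -1.034 for the matrix targets, -0.4667 for collagens, -0.2609 for collagen processing, -0.594 for matrix glycoproteins, -0.1552 for TGF-beta response, -1.537 for interferon response, -0.4061 for fibroblast markers, -0.4587 for T or NK markers and 0.2776 for cell cycle. Camera's adjusted p ran from 8.8e-22 to 0.035, and none of the 9 passed with an estimated correlation (adjusted p from 0.44 to 0.76). The TGF-beta difference no longer passed without incised PBS 3 (-0.18), mimic 3 (-0.04), intact PBS 2 (-0.16), intact PBS 3 (-0.15) or antimiR 1 (-0.16). The cell cycle difference did not without incised PBS 1 (0.20), mimic 2 (0.22), intact PBS 1 (0.08), intact PBS 2 (0.12), antimiR 2 (0.24) or antimiR 3 (0.21), and the fibroblast difference did not without antimiR 1 (-0.32). Without intact PBS 3 the cell cycle difference was 0.69. Collagen processing was at -0.17 without mimic 3, -0.12 without intact PBS 3 and -0.15 without antimiR 1, and TGF-beta response at -0.23 without mimic 1. Over 14 processing alternatives the TGF-beta call ended in 8 (medians from -0.18 to -0.03) and the cell cycle call ended or reversed in 5 (from -0.45 to 0.63). Incised and intact skin differ between the 2 effects as well as the oligonucleotide, so this difference does not separate them. Of 100 splits, the real one included, 9 gave as many genes as the real one or more, again with the real one included, and up to 1934, so chance was not excluded by this count. All 9 were among the 13 that kept the real grouping of the intact arrays, of which the real split is 1. The 87 that mixed those arrays gave 0 each. The count thus followed the grouping of the intact arrays. Splits that keep this grouping carry its difference by design, and it is partly a grouping by slide. The splits therefore do not show whether antimiR or slide lies behind the count.

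Upstream probes lost signal in the antimiR arrays. A loss of whole transcripts moves both probes of a gene alike, and the difference over all pairs was -0.1388. The 95% interval of -0.149 to -0.129 is over probe pairs and does not measure the spread between arrays. Per array the median was -0.132, -0.143 and -0.145 with antimiR, and 0.009, 0.040 and -0.022 on intact PBS arrays 1, 2 and 3. Each antimiR array lay below the PBS array of slide 3, the nearest by -0.1373 for pairs 5 to 20 kb apart, which counts against slide 3 as the whole cause, but that is 1 array, so slide 3 is not excluded. Pairs over 20 kb apart, at -0.1633, had been meant to set aside other polyadenylation sites within a last exon. Use of such sites can move the downstream probe against any upstream probe, so these pairs do not decide it. Shorter RNA or a shorter labelled product in the antimiR arrays is another candidate explanation that these tests left standing, at -0.1506 for pairs 5 to 20 kb apart. Premature ends of transcription were not tested.

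The matrix targets were lower with mimic. Within slide 1 the median was -0.6355, and the list kept its call in all 15 processing alternatives, slide as a block among them (medians from -0.75 to -0.61, adjusted p at most 1.6e-07). These calls used camera's preset correlation of 0.01. In the main fit the adjusted p was 0.25 with an estimated correlation and 0.081 with fry. The medians, which stayed negative, count against slide as the whole cause. The value adjusted for slide rests on 1 mimic array against 3 PBS arrays, so slide is not excluded. The tables argue against shorter RNA, with an upstream minus downstream difference of -0.006369. The targets lay -0.3808 below other fibroblast and matrix genes (medians -0.69 and -0.31, 1-sided permutation p = 0.0029 over genes), which had been set beforehand as evidence against less fibroblast RNA. Genes are not independent replicates, so this p does not measure the spread between arrays. That comparison set held genes of other cell types, and the fibroblast markers themselves had a median of -0.80, as low as the targets. Repression of its targets by miR-29 and a smaller share of fibroblast RNA in the mimic skin therefore cannot be told apart here. With antimiR the same comparison gave medians of 0.35 and 0.02, a difference of 0.33 (1-sided permutation p = 0.0011, again over genes). Fibroblast markers were at -0.36 there. The antimiR shift of the targets rested on intact PBS array 3, so this does not decide it.

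The interferon response genes were higher with antimiR. Within slide 3 the median was 2.135, which had been set beforehand as evidence against slide. The list kept its call in all 15 processing alternatives (medians from 1.89 to 2.13, adjusted p at most 2.6e-16), and the PBS array on slide 3 had the lowest interferon score of the intact PBS arrays (-1.38, against -0.91 and -1.05). These calls used camera's preset correlation. In the main fit the adjusted p was 0.67 with an estimated correlation and 0.0035 with fry. The medians and scores count against slide 3 as the whole cause, but that slide held 1 PBS array, so slide is not excluded. Only Cxcl9, Herc6, Xaf1, Ifih1, Zbp1, Oas1a and Cxcl10 had probes at least 500 bp apart, with 605 bp for Cxcl9 and 547 bp for Ifih1. Over their upstream probes the median was 1.391, with -0.107 for Cxcl9 and 1.035 or more for the others. For these genes as a set this argues against a rise at downstream probes alone, as shorter RNA would give. The other interferon genes were not covered. The macrophage, neutrophil and T or NK lists reached at most 0.1379 of the interferon median, which argues against a larger share of these cells as the whole cause. The macrophage list was split, however, with 6 of 19 markers called higher. Its upper quartile of 1.382 lay only just below the lower quartile of the interferon list, 1.386. Monocytes had no list and stay open. A response to any injected oligonucleotide could not be separated from blocking of miR-29, since no control oligonucleotide was injected. With mimic the median was 0.3389, in incised skin where these genes were already high.

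The splits of 3 against 3 arrays number 10, too few for a share under 0.05. The real grouping was the 1 split with the highest count for mimic (119, highest other 0), for antimiR (1986, highest other 6) and for wounding (3140, highest other 0). It was also the 1 highest for the matrix targets with mimic (0.6894, highest other 0.392) and the interferon genes with antimiR (1.972, highest other 0.9279). For the matrix targets with antimiR 4 of the 10 splits were as large (0.3472, highest other 0.5564). In the Cy3 reference channel alone limma called 9 genes between the antimiR and PBS arrays, 15 between the PBS groups, and 0 for mimic and for the difference. At an unadjusted p under 0.05 there were 1601, 1168, 544 and 926 of 20320 genes in this order. Of the genes called in the ratio, 4 of 1986 and 11 of 3140 were also called in Cy3, so calls in the reference channel do not account for most of them.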

How the results depend on the processing

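The downstream probe was the one alternative chosen after the data were seen, and all others were set before the data were examined. Slide blocks, array weights, other signals, backgrounds, scalings, filters and single arrays left out were tried. The number of list calls stayed at 41 to 57 and the correlation between the mimic and antimiR effects at 0.26 to 0.46. These list calls all used camera's preset correlation and depended on it. In the main fit it called 14, 10, 14 and 9 lists for mimic, antimiR, wounding and the difference. Fry called 2, 1, 7 and 0, and camera with an estimated correlation called 0 in each. Leaving aside the fits without 1 array, of 733 values for named genes with antimiR 657 kept direction and side of the threshold, with mimic 431 of 536, with wounding 492 of 568 and in the difference 191 of 224. For lists these were 134 of 165, 208 of 225, 230 of 240 and 126 of 140. With 1 array left out the shares for genes were lower in all 4 contrasts: in the same order 249 of 294, 131 of 216, 189 of 228 and 142 of 192 for genes, and 54 of 66, 77 of 90, 92 of 96 and 108 of 120 for lists. The shift of genes with a miR-29 seed match was not run, since no 3' UTR sequences were available. Where values changed, the cause was not tested unless stated.

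The count of 119 genes for mimic was 38 (14 higher, 24 lower) with Feature Extraction processed signals, 44 (17 and 27) with Cy5 alone, 38 (13 and 25) with the deposited table, 439 with only the compared groups fitted, 69 with trend and robust moderation, 708 (337 and 371) with array weights, 0 with slide as a fixed block (1471 at an unadjusted p under 0.05), 58 with slide as a random block and 76 with the replicate block. For scaled arrays it was 133 (63 and 70). For antimiR the count was 1205 (774 and 431) with Cy5 alone and 538 with only the compared groups, and 1829 (840 and 989) with the deposited table. For wounding it was 1738 (1062 and 676) with Cy5 alone, 1354 (1006 and 348) with only the compared groups and 11 with slide as a fixed block. For the difference it was 377 (246 and 131) with Feature Extraction processed signals, 78 (39 and 39) with Cy5 alone, 300 (211 and 89) with the deposited table, 463 with array weights, 17 with slide fixed and 127 with slide random. A fit of only the compared groups has fewer arrays for the spread, and slide as a fixed block leaves few arrays to compare within a slide. For wounding it leaves none, and that estimate runs through the mimic arrays of slides 1 and 2.

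Leaving out 1 array gave 1 to 53 genes for mimic, 1.1e+03 (rounded, without antimiR 2) to 2103 for antimiR, 1690 to 2963 for wounding and 66 to 439 for the difference, with fewer arrays as part of the cause. Wounding gave 1690, 1893 and 1874 without incised PBS 1, 2 and 3. The difference gave 66 and 114 without incised PBS 1 and 3, 127, 92 and 100 without mimic 1, 2 and 3, 439 without intact PBS 3, and 119 and 140 without antimiR 2 and 3. Array weighting gave intact PBS 3 a weight of 0.272.

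The matrix targets' median with antimiR was 0.15 (adjusted p = 0.063) with the deposited table and 0.20 (0.14) with array weights, and ran from 0.18 to 0.54 with 1 array left out. The lists that reversed were these: epidermal differentiation was at 0.044 with mimic for Cy5 alone and 0.25 with antimiR for slide fixed, other targets with antimiR at -0.042 with the deposited table and -0.012 for slide fixed, T or NK markers at -0.0016 with wounding and cell cycle at -0.45 in the difference for slide fixed, and adipocyte markers with mimic ran from -0.86 to 0.13 with 1 array left out, reversing without incised PBS 2.

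Single genes reversed as follows. Dnmt3b with mimic was at 0.052 with Feature Extraction processed signals, 0.26 with Cy5 alone, 0.0050 with array weights and -0.043 to 0.036 with 1 array left out. Fbn1 with antimiR was at 0.011 with Feature Extraction processed signals, 0.074 with Cy5 alone, 0.011 with the deposited table, 1.24 with slide fixed, 0.14 with slide random and -0.66 to 0.45 with 1 array left out. With antimiR, Ccl3 was at -0.33 with Cy5 alone (adjusted p from 5.9e-05 to 0.90 over its alternatives). With 1 array left out Col3a1 ran from -0.21 to 1.11 and Eln from -0.013 to 0.51. Signal over background of 3.63 to 4.99 limits the precision of weak probes, and sample numbers did not pair the groups (correlations from -0.44 to 0.29).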

Other observations

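Genes of oxidative phosphorylation and skeletal muscle had lower medians with both oligonucleotides, -0.21 and -0.64 with mimic and -0.32 and -0.36 with antimiR. For skeletal muscle all 19 markers were negative in both. In simulated changes of 1 on the log2 scale, 83.6% of genes were called for mimic, 70.1% for antimiR and 82.1% for wounding.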
